A study of Drosophila melanogaster with 3 samples.

How the data were processed

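ChIP-seq for a Pif1B-eGFP fusion was done with an anti-GFP antibody on sonicated chromatin of whole pupae, per the labels. The labels number 3 biological replicates of 1 group, each from its own biosample with both sexes pooled. Per the deposited text files, a relaxed list of peaks and background was called for each replicate against a control, another on the pooled replicates, and the IDR-thresholded list was derived from these lists. The aligner, the peak caller and the IDR threshold are not given in the sources used here, and the control libraries were not analysed here. The lists came in the builds dm6 and dm3, per the labels. In each deposited list the value used was the signal of each region, in the signal column of the narrowPeak format, as the authors' peak caller wrote it; the score and p-value columns held constants. The IDR list was found to hold the 6410 regions of the pooled list with the highest signal, all at or above 83.2, with the same values. In 73.5% of the IDR peaks the width was 430 bp, and in 74.0% the summit was at the middle of the interval. Summits may therefore be placed less precisely there, which was not tested. No 2 replicates had identical intervals.

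Because the relaxed lists hold nearly the same number of regions for every replicate, they carry no information on depth, and signal values were not compared between replicates other than by rank, except in the closing observations on chromosome X. All coordinates are in dm6, 1-based. Regions of dm6 lay inside the lengths of the reference chromosomes, and genes and transcription starts came from the Ensembl annotation of the BDGP6 assembly, with transposable elements left out, and sequence from the RefSeq release of the same assembly. Results on dm3 are limited to those that need no annotation. Of 312 list entries, 3 matched no gene in the annotation.

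Analyses were run in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9. Groups, tests, gene lists, motifs and alternatives were fixed before the data were examined. A replicate supported a peak when they overlapped by at least 1 bp among its 6410 strongest regions. A promoter was any summit within 500 bp of an annotated start. Promoter and X shares were compared with the 22032 relaxed pooled regions on the chromosome arms that overlapped no IDR peak by two-sided Fisher's exact tests. Odds ratio intervals are Woolf intervals, with 0.5 added where a count was 0. Shares carry 95% Clopper-Pearson intervals. A protein-coding gene was bound when an IDR summit lay within 500 bp of a start, and the background was the genes with a pooled relaxed summit there. The 23 lists were ribosomal, mitochondrial ribosomal, proteasome, oxidative phosphorylation, translation initiation, cell cycle, ecdysone, Hox, developmental, E(spl) and achaete-scute, heat shock, cuticle, chitin, muscle, nervous system, photoreceptor, testis, chemoreceptor, haemocyte, fat body, chromatin, histone and Pif1B partner genes. Motifs (36 consensus sequences) and all 2080 hexamers, merged with their reverse complements, were searched on both strands within 50 bp of a summit and in a window 500 bp to a random side, and compared by exact McNemar tests with Benjamini-Hochberg adjustment. Annotation classes were assigned to each summit in the order promoter, 5' untranslated region, coding sequence, 3' untranslated region, noncoding exon, intron and intergenic.

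The text names the genes at the 20 strongest IDR peaks (starts within 500 bp, otherwise the nearest start), the 5 strongest distal peaks, Pif1B and Pif1A, the 4 bound members with the strongest promoter peak of each list past its test (for a list bound less often, 4 unbound members in alphabetical order) and the 10 hexamers of largest ratio. Other named genes, hexamers and decamers were chosen after their values were seen, among them the members of lists that did not pass.

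The tests were checked on simulated data. With promoter odds ratios of 1, 2 and 3 built into 22032 regions, the median estimates over 50 draws were 1.00, 1.98 and 2.98. When 3 lists among 4676 genes were set to be mostly bound, 100% of them and 0.700% of the other lists were called. These were the ribosomal, developmental and mitochondrial ribosomal lists, with 54, 40 and 26 compared genes. Their simulated bound share was above the 66.7% of the ribosomal list in the data. Power for shorter lists or smaller differences was not checked. All 6 motifs planted in 6410 windows were called, with 1 of the 30 others, and no hexamer was called without planted words. Each motif was planted in a larger share of windows than held the DRE (0.468%) or CLAMP site (0.452%) at summits. Power for motifs that rare was not checked. Both sets of windows were drawn away from the summits, with no difference in GC content built in. The check therefore says nothing on motif and hexamer calls that come from base composition. Alternatives were other distances to starts, other overlap rules, the 3205 peaks with the highest signal, peaks with support from all 3 replicates, other backgrounds, dm3 lists and leaving out each replicate. For a single-group result the last means peaks supported by both other replicates. These peaks are a part of the same IDR list, so bound genes and summit windows can only become fewer. A call lost in this way does not by itself show dependence on the replicate left out. The GC-matched windows (the nearest in GC among windows 300 to 3000 bp from the summit, in steps of 50 bp), lists without misplaced members and X shares per replicate were added after seeing the data.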

Results

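Chromatin bound by a tagged form of Pif1B was mapped in whole pupae of Drosophila melanogaster, the fruit fly. Pif1B, whose name stands for PFTAIRE-interacting factor 1B, carried a green fluorescent protein at its C-terminal end, and bound DNA was recovered with an antibody against that tag and sequenced (chromatin immunoprecipitation with sequencing, ChIP-seq). There was 1 group of 3 biological replicates, each a pool of male and female pupae, and no other stage, tag or condition. The comparisons that this design allows were made between the replicates and, within the peak lists, between peaks that passed the authors' reproducibility threshold (irreproducible discovery rate, IDR) and weaker regions of the same libraries. Each replicate had a relaxed list of 29999, 29999 and 30000 regions in the dm6 build of the genome. The pooled libraries had a relaxed list of 29999 regions and the IDR list held 6410 peaks with a median width of 430 bp, of which 779 overlapped another peak of the list. Only peak lists were analysed here, so the sequencing depth of each library is unknown. Peak signal values are the authors' own and rank peaks within a list.

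The strongest binding lay at genes of varied function. The first peak of the IDR list, with a signal value of 1933, was at the start of Ugalt, which encodes a UDP-galactose transporter (chromosome X, 2703685 to 2704092, dm6, summit 28 bp outside the gene). The next were a peak of 1871 at the start of CG14100 (3L, 19590435 to 19590801) and a peak of 1865 in an intron of CG11050 (2L, 6612400 to 6612915). A peak of 1861 lay at a start of PNPase, a polynucleotide phosphorylase (3R, 31404484 to 31404856). An intron of ush, which encodes a cofactor of GATA factors, held a peak of 1628 whose nearest start, 1367 bp away, was that of cbt (2L, 480895 to 481336). A peak of 1626 lay at a start of larp, a La-related RNA-binding protein (3R, 28326332 to 28326836). Further down the first 20 were the start of CG18549 (1522), the shared promoter region of Chro, a chromodomain protein of interband chromatin, and Ssl1, a subunit of the transcription factor TFIIH (1430), the region between CenG1A and mRpS23 (1430), Hsp27 (1415), lncRNA:CR31044 (1364), Fbw5 and CG9147 (1299), CG1888 (1187), CG13921 (1164) and a peak at the start of CG32772 (1159).

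Of the first 20 peaks, those at distance from any start included an intron of CG32772 (1446), an exon of lncRNA:CR46035 inside osa, which encodes a subunit of the Brahma remodelling complex (1369), and an intron of Lk6, a protein kinase (1354). An intron of dnr1 held a peak of 1261 that lay 7.71 kb from the nearest start, that of CG11362, and an intron of CG9663 one of 1160. All of these peaks were supported by 3 of 3 replicates. The Ugalt peak ranked 2, 3 and 1 in the relaxed lists of replicates 1, 2 and 3, and the CG11050 peak 4, 1 and 4. The dnr1 peak ranked 9 and 8 in replicates 1 and 3 but 147 in replicate 2.

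The first comparison asked how well the replicates shared these sites. A peak was counted as supported by a replicate when at least 1 bp of it overlapped 1 of the 6410 strongest regions of that replicate. Replicates 1, 2 and 3 supported 85.1%, 81.7% and 86.2% of the IDR peaks (84.4% ± 2.32, SD, n = 3). All 3 replicates supported 4207 of 6410 peaks, or 65.6% (95% Clopper-Pearson interval 64.5 to 66.8). A further 22.9% had support from 2 replicates, 10.4% from 1 and 1.08% from none. These intervals, here and below, cover counting error only, and peaks are not replicates.

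Support followed peak strength. In the strongest decile of the IDR list, with a median signal value of 470, 99.1% of 641 peaks were supported by all 3 replicates (interval 98.0 to 99.7). The share was 86.7% in decile 5 and 9.67% (7.50 to 12.2) in the weakest decile, whose median signal value was 86.7. Peaks near the threshold of the IDR list can miss the equally long list of a replicate by little. When the whole relaxed lists were used, 98.5% of the IDR peaks and 96.7% of the weakest decile were supported by all 3 replicates, against 42.2% of the 22032 pooled regions that overlapped no IDR peak. The IDR list was derived from the lists of these same replicates and holds the strongest pooled regions. High support, its rise with signal and its excess over the other regions are therefore in part built in. Across IDR peaks, the signal values of the strongest overlapping regions had Spearman correlations of 0.70 between replicates 1 and 2, 0.77 between 1 and 3 and 0.73 between 2 and 3 (mean 0.73). These are correlations across 6340 to 6350 peaks, which are not independent replicates. The share supported by all 3 replicates fell to 53.9% when summits had to lie within 100 bp of each other.

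**Figure D1:**
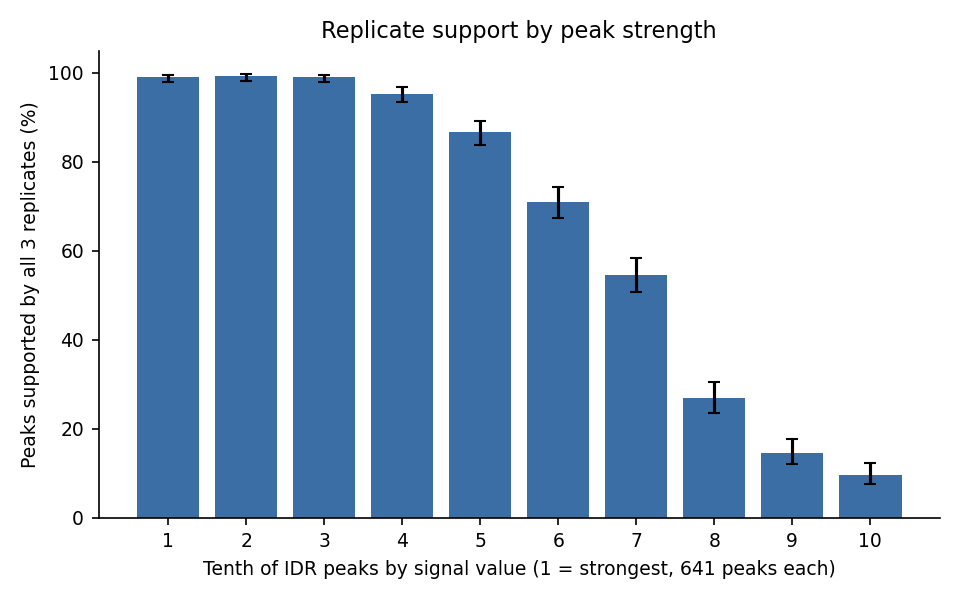
Percent of IDR peaks supported by all 3 replicates (y axis) in each decile of the IDR list ordered by signal value (x axis, 641 peaks per bar), with 95% Clopper-Pearson intervals. The bars fall from 99.1% in the strongest decile to 9.67% in the weakest.

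The second comparison asked where in the genome the peaks lay. IDR peaks were at promoters more often than weaker regions were. A summit lay within 500 bp of an annotated transcription start in 2386 of 6410 IDR peaks (37.2%, interval 36.0 to 38.4) and in 4389 of 22032 relaxed regions that overlapped no IDR peak (19.9%, interval 19.4 to 20.5). The odds ratio was 2.38 (2.24 to 2.53; two-sided Fisher's exact test across regions, p = 2.86e-168). In each replicate alone the 6410 strongest regions were also more often at promoters than the rest of its list, with means of 39.1% ± 2.28 and 22.8% ± 1.34 (SD, n = 3), and this held in 3 of 3 replicates. When the IDR summits were shifted along the chromosome arms, a mean of 13.6% fell at promoters, with a maximum of 15.6% over 1000 shifts.

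Introns held 43.5% of the IDR summits and 49.4% of the relaxed ones, and intergenic sequence 1071 of the 6410 and 5513 of the 22032 (Fisher's exact adjusted p = 2.69e-16 and 1.44e-45 over 7 classes). The classes are exclusive and promoters were assigned first, so a larger promoter share lowers the other shares. The lower intron share therefore does not show that introns were avoided among summits away from promoters. Introns held 2791 of the 4024 IDR summits away from promoters and 10877 relaxed summits. Shares among such summits were not tested. Coding sequence away from promoters held 6 IDR summits, or 0.0936%, against 1.26% of relaxed summits (exact adjusted p = 4.47e-23), and 3' untranslated regions held 0.686% against 2.31% (adjusted p = 7.06e-20). Among protein-coding genes on the chromosome arms, 2180 of 13945 had an IDR summit within 500 bp of a start.

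**Figure D2:**
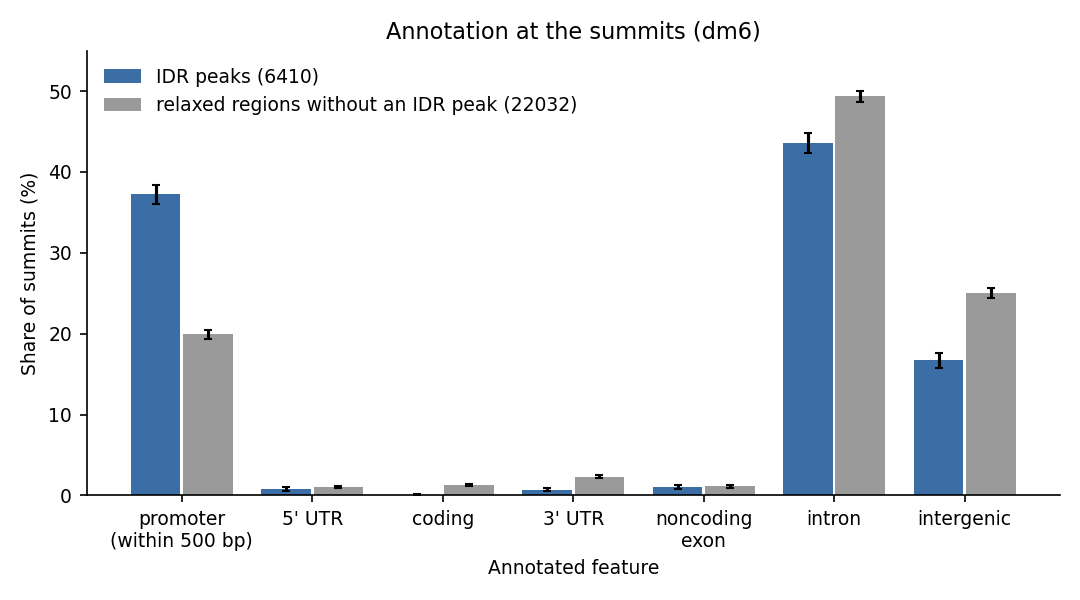
Share of summits (y axis, percent) in each class of annotation (x axis) for IDR peaks (blue) and for relaxed regions that overlap no IDR peak (grey), with 95% Clopper-Pearson intervals. Promoters hold 37.2% of IDR summits and 19.9% of relaxed summits.

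Promoter peaks were only slightly stronger than distal ones. The median signal value was 141 at 2386 promoter peaks and 135 at 4024 distal peaks, a difference of 0.07 on the log2 scale (two-sided permutation test across peaks with 100000 resamples, p = 0.00624). The upper end differed more, with 90th percentiles of 405 and 321, and promoters made up 50.7% of the strongest decile of peaks (interval 46.8 to 54.6). The difference in medians was no longer past the threshold of the permutation test with starts taken within 250 bp (p = 0.558), with ranks averaged over replicates in place of signal (p = 0.109), or among peaks supported by replicates 1 and 2 (p = 0.0583). It was larger among peaks supported by all 3 replicates (0.13, permutation p = 1.40e-04) or by replicates 2 and 3 (0.11, p = 6.00e-05).

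The share of peaks on the X chromosome had an odds ratio near 1 against weaker regions. The X held 1232 of the 6386 IDR peaks on chromosomes X, 2 and 3 (19.3%, interval 18.3 to 20.3) and 19.1% of the relaxed regions, with an odds ratio of 1.01 (interval 0.944 to 1.09; Fisher's exact test, p = 0.718). Density was 52.3 IDR peaks per Mb on X, 49.6 on 2L, 43.7 on 2R, 50.6 on 3L and 45.6 on 3R. The small chromosome 4 held 24 peaks, or 17.8 per Mb, and the Y held none, with no relaxed region either. Against the number of bases of the arms in place of relaxed regions, the X share was higher (log2 odds ratio 0.15, exact binomial p = 0.00158).

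The third comparison asked which groups of genes were bound at their promoters. Of 4676 protein-coding genes with a relaxed summit within 500 bp of a start, 2180 (46.6%) had an IDR summit there. Of 23 gene lists, 3 passed a two-sided Fisher's exact test across genes with Benjamini-Hochberg adjustment, and 7 had an unadjusted p under 0.05. Genes are not replicates, and these tests describe 1 set of libraries.

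Heat shock genes, which encode chaperones, were bound more often than other genes. Of 25 list members, 11 had a relaxed summit within 500 bp of a start and could be compared. Over all 25 members, 44.0% were bound, against 15.6% of other protein-coding genes (exact adjusted p = 0.00269). All 11 compared were bound (100% against 46.5%, exact adjusted p = 0.00257), through 10 separate peaks, with neighbouring genes counted singly. The strongest were at Hsp27 (1415), Hsp26 (403), Hsp83 (392) and Hsc70-5 (184). Hsp22 and Hsp67Bc shared a peak. Of these genes, 7 had a peak supported by all 3 replicates. The call was lost among peaks supported by replicates 1 and 3 (exact adjusted p = 0.221) or by replicates 1 and 2 (adjusted p = 0.218), with starts taken within 250 bp (adjusted p = 0.657), among the 3205 strongest peaks (adjusted p = 0.679) and among peaks with full support (adjusted p = 0.200). With all 11 bound in the main analysis, a part of the same peaks could only leave fewer bound. Over all alternatives the exact adjusted p ranged from 0.00257 to 0.679.

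Ribosomal protein genes, with 93 list members, were also bound more often. Of the 54 that could be compared, 36 were bound (66.7%, odds ratio 2.31, interval 1.31 to 4.08, exact adjusted p = 0.0279). Their strongest peaks were at RpL32 (419), RpL24 (279), RpS10b (229) and RpL7 (219), and the median over the 36 was 142. Only 21 of the 36 had support from all 3 replicates. The list did not pass the test when any replicate was left out (exact adjusted p from 0.0720 to 0.818), nor with starts taken within 1000 bp (adjusted p = 0.0573), among the 3205 strongest peaks (0.400) or among peaks with full support (0.503). Leaving out a replicate keeps a part of the same IDR peaks, so the 36 bound members could only become fewer. The odds ratio was 1.43 without replicate 1, 1.28 without replicate 2 and 2.13 without replicate 3. Over all alternatives the exact adjusted p ranged from 4.33e-07 to 0.818. The mitochondrial ribosomal proteins did not pass, with 14 of 26 bound (exact adjusted p = 0.710), although the median signal value of those 14 peaks was 260.

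Cuticle protein genes, which encode the structural proteins of the insect exoskeleton, were bound less often. Of 121 list members, 19 had a relaxed summit at a start, and none of these had an IDR summit there (exact adjusted p = 1.58e-04). Acp65Aa, Cpr100A and Cpr12A were among the unbound members, with relaxed signal values of 24.8, 37.8 and 42.0. Cpr, also unbound at 75.9, encodes cytochrome P450 reductase and entered the list by its name alone. Without it, 0 of 18 were bound (exact adjusted p = 3.01e-04). The list lost its call with starts taken within 250 bp (exact adjusted p = 0.114) and among the 3205 strongest peaks (adjusted p = 0.0805). When each replicate was left out the call stayed, with exact adjusted p from 0.00854 to 0.00984. That outcome says nothing on stability. The peaks left are a part of the same IDR list, so 0 of 19 could not change. Over all alternatives the exact adjusted p ranged from 1.77e-08 to 0.114.

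The other lists did not pass the adjusted test. Genes of the ecdysone cascade, the steroid hormone response that drives metamorphosis, had 15 of 20 members bound (75.0%, odds ratio 3.45, exact adjusted p = 0.0626), among them E23 (622), Ldh (483), Eip75B (479), Eip93F (372), Eip74EF (200), EcR (155) and usp (125). The odds ratio of this list was 1.93 without replicate 1, 3.46 without replicate 2 and 2.23 without replicate 3. This list passed with starts taken within 1000 bp (exact adjusted p = 0.0188) and against all protein-coding genes (2.44e-06), and over all alternatives the adjusted p ranged from 2.44e-06 to 0.436. Chemoreceptor genes had 1 of 11 bound, Gr77a (exact adjusted p = 0.0626), and passed in the same 2 settings (0.0464 and 5.74e-11, range over all alternatives 5.74e-11 to 0.370). None of the 6 Hox genes compared was bound (exact adjusted p = 0.128), and their strongest relaxed region, at Scr, had a signal value of 62.7. Nervous system genes had 3 of 16 bound, which were elav (605), comt (130) and Ddc (95.6; exact adjusted p = 0.135). Chromatin and insulator factors had 10 of 15 bound (exact adjusted p = 0.329), including Chro (1430), the Polycomb group gene ph-p (856), brm (526), E(z) (294), trx (212) and Trl, which encodes GAGA factor (198). Developmental regulators had 16 of 40 bound (exact adjusted p = 0.659), led by tin (496), hb (316), Dll (248) and hry (210).

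Among the remaining lists, 5 of 8 genes of the E(spl) and achaete-scute complexes were bound, 3 of 4 fat body genes, 6 of 10 replication and cell cycle genes (5 of 8 without Orct and Orct2, which entered by name alone), 8 of 15 translation initiation factors and 8 of 22 genes each for oxidative phosphorylation and chitin metabolism. The counts were 4 of 9 for muscle, 1 of 5 for the proteasome, 1 of 6 for haemocytes, 1 of 3 for photoreceptors, 1 of 2 for histones and 0 of 4 for testis. Their exact adjusted p-values ranged from 0.329 to 1. Against all protein-coding genes the histone (exact adjusted p = 5.75e-07), proteasome (0.0152) and testis (0.0187) lists passed as bound less often, and these 3 passed in no other alternative. Few of their genes had a relaxed summit at a start (2 of 115, 5 of 48 and 4 of 32). Genes without any region, for whatever reason, count as unbound in that setting. Pif1B and its named partners had 2 of 4 bound, and the 2, Pif1A and Pif1B, shared a peak.

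**Figure D3:**
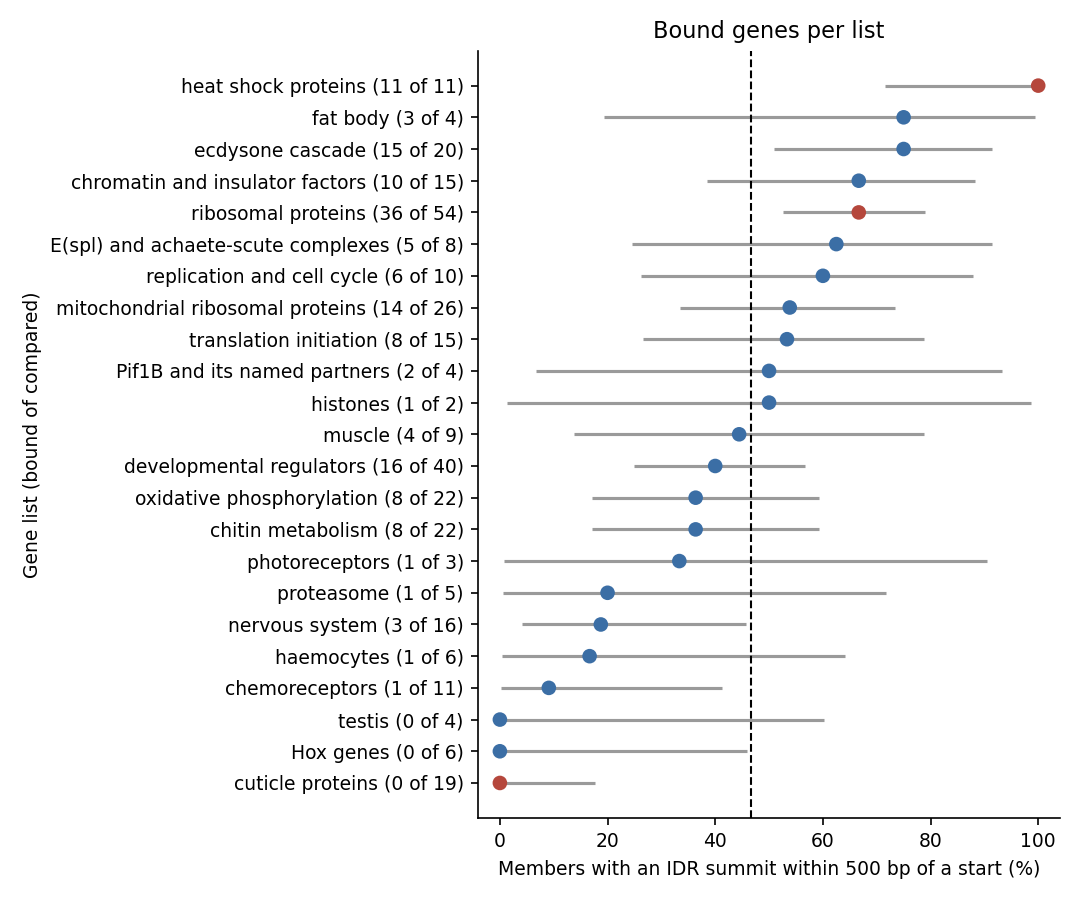
Percent of compared genes with an IDR summit within 500 bp of a start (x axis) for each of 23 gene lists (y axis, with the counts), with 95% Clopper-Pearson intervals. The dashed line marks 46.6%, the share over all 4676 compared genes, and red points mark the 3 lists past the adjusted test, with heat shock proteins at 100% and cuticle proteins at 0 of 19.

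The tagged gene's own locus held IDR peaks. The flies carried a tagged transgene, which adds a copy of this locus. Signal there can therefore come from copy number, and binding to the gene itself was not told apart from it. Pif1B and Pif1A share 1 span on the minus strand of 3R (8774286 to 8801176), and 3 IDR peaks lay inside it. The strongest, with a signal value of 617 and rank 158, lay in an intron (8789061 to 8789351). The second, at 259 and rank 1138, lay 183 bp from a start that both genes use (8792515 to 8792944). The weakest, at 108, was intronic and supported by 2 replicates (8791248 to 8791677). A 20 kb window centred on the gene therefore held 3 IDR peaks, the 86.2 percentile of 5118 windows with at least 1 relaxed region, which held 1.25 IDR peaks on average and 12 at most.

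**Figure D4:**
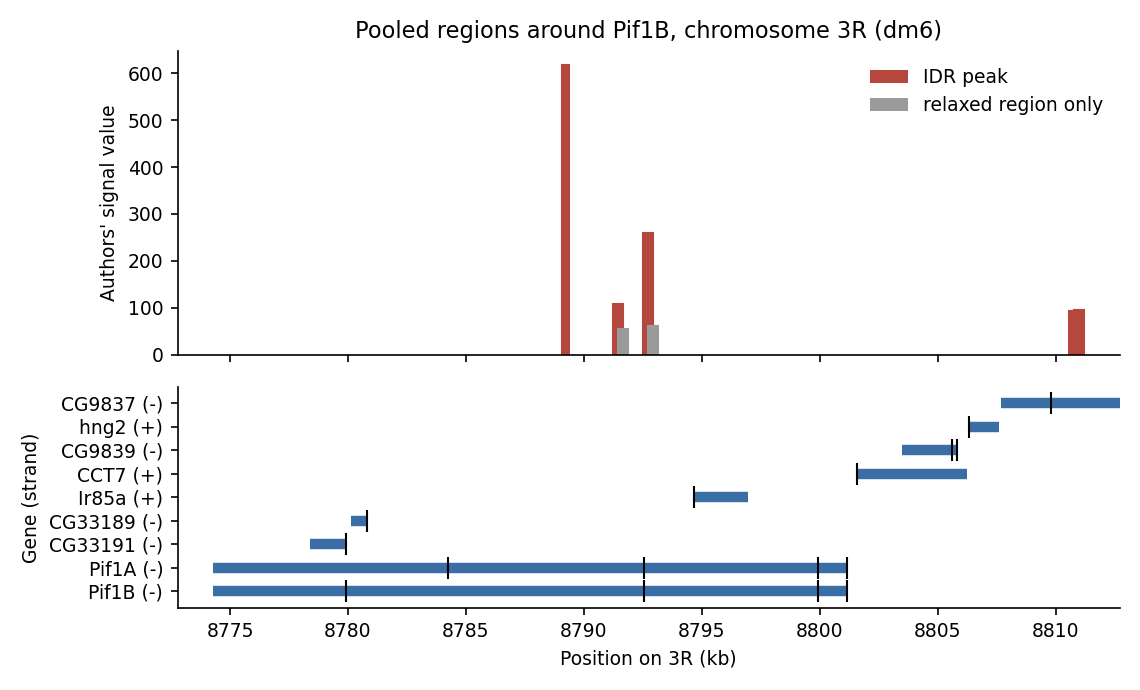
Regions of the pooled list around Pif1B on 3R, with signal value (upper y axis) against position in kb (x axis); IDR peaks are red and relaxed regions grey. Blue bars below are protein-coding genes with their strand and black ticks are annotated transcription starts; the highest of the 3 IDR peaks inside Pif1B has a signal value of 617.

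The last comparison asked which sequences mark the summits. Summits were AT-rich: windows of 101 bp at the summits of the 6410 IDR peaks had a mean GC content of 35.5%, against 42.7% in windows 500 bp away. Of 36 motifs, 9 were more frequent at summits and 7 less frequent than in those flanking windows (two-sided exact McNemar test across peaks, Benjamini-Hochberg adjusted p under 0.05). Runs of 8 A were found at 10.8% of summits and 6.13% of flanks (exact adjusted p = 1.06e-20), GATA sites at 15.5% and 11.2% (adjusted p = 1.01e-11), the TATA box at 4.45% and 2.46% (adjusted p = 4.19e-09) and the homeobox site TAATTA at 8.60% and 5.73% (adjusted p = 2.48e-09). GAGA, the site of GAGA factor, was found at 4.02% and 2.54% (exact adjusted p = 1.09e-05). The DRE, the Ohler motif 7, the Hox-Exd and the forkhead sites were the others that were more frequent (exact adjusted p from 0.0348 to 0.0434). GC box, E-box, CA repeat, tramtrack, CACGTG, Sd and ETS sites were less frequent at summits, the GC box at 1.58% and 3.98% (exact adjusted p = 5.39e-16). When 1 replicate was left out, Ohler motif 7 (exact adjusted p from 0.113 to 0.174) and Sd (0.121 to 0.804) lost their calls each time, DRE without replicate 1 (0.542) or 2 (0.501), forkhead without replicate 1 (0.0666) or 3 (0.160), and ETS without replicate 1 (0.174). Log2 ratios then went from 0.53 to between 0.43 and 0.48 for Ohler motif 7, from -0.67 to between -0.46 and -0.14 for Sd, from 1.18 to 0.57 for DRE, from 0.39 to 0.44 and 0.34 for forkhead and from -0.98 to -0.77 for ETS. Against relaxed regions in place of flanks, TATA (exact adjusted p = 0.107), homeobox (0.251), A run (0.0966) and Hox-Exd (0.962) also lost their calls, and CACGTG did so in windows within 100 bp (0.0950), among the 3205 strongest peaks (0.288) and among peaks with full support (0.126). Over all alternatives the highest exact adjusted p was 0.569 for DRE, 0.658 for Ohler motif 7, 0.995 for forkhead, 0.804 for Sd, 0.256 for ETS, 0.962 for Hox-Exd, 0.310 for CACGTG, 0.894 for TATA, 0.251 for homeobox and 0.121 for the A run.

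Fewer motifs differed when base composition was matched. Against windows matched to each summit in GC content within 3000 bp, a comparison chosen after seeing the data, 2 motifs were more frequent and 1 less, from 9 and 7 against flanks. GAGA was found at 4.02% of summits and 1.51% of matched windows (exact adjusted p = 1.28e-17), and the CLAMP site, a GA-rich motif, at 0.452% and 0.125% (adjusted p = 0.00903). The tramtrack site was found at 4.43% and 6.02% (exact adjusted p = 8.17e-04). GATA was then at 15.5% and 15.4% (exact adjusted p = 0.990) and the A run at 10.8% and 9.63% (adjusted p = 0.121). GAGA missed the threshold against flanks in the 3205 peaks with the highest signal (exact adjusted p = 0.288).

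Hexamers showed the same division. Of 2080 hexamers, 417 were more frequent at summits than in flanks and 911 less frequent. The 10 with the largest ratio were ATATTA, TAGTAA, CTAGTA, TACTAA, ATATAT, AATATA, AGTGTA, AAGCTT, TTTAAA and TATTAA. ATATTA was found at 18.5% of summits and 8.03% of flanks, and TATTAA at 17.4% and 8.64%. Of the 228 hexamers with no more than 1 G or C, 221 were more frequent. Against GC-matched windows 103 hexamers were more frequent and 95 less, and 43 of the 103 were also more frequent against flanks. The largest ratios were then at AGAGCG (6.54% and 2.76%), GAGCGC (3.62% and 1.56%), GAGAGC (6.90% and 3.24%) and AGAGAG (8.52% and 4.07%).

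**Figure D5:**
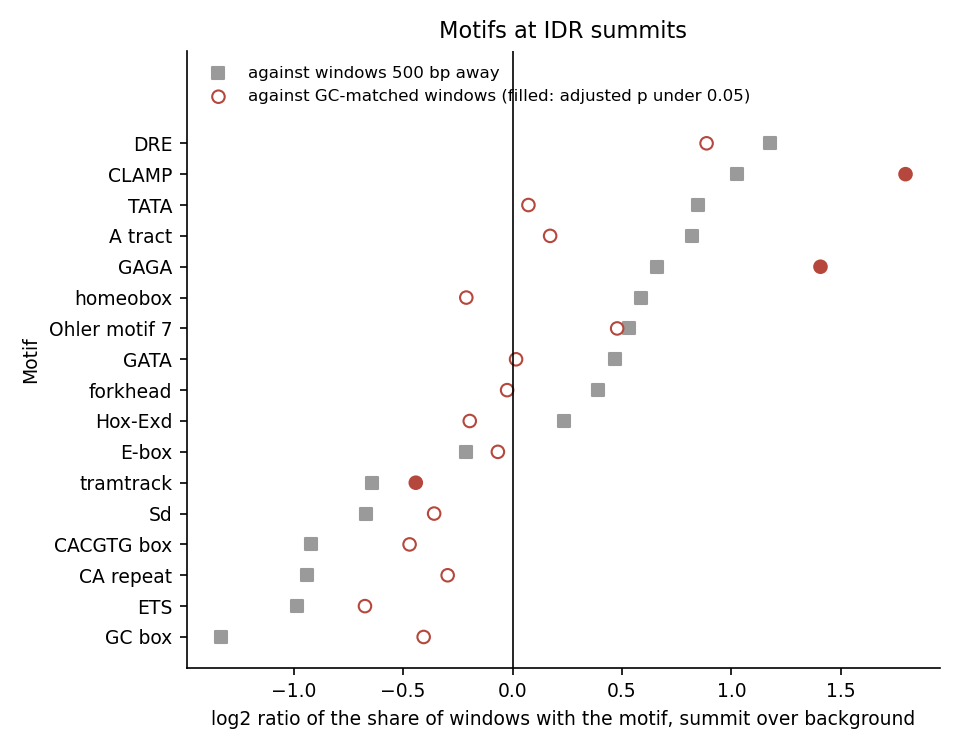
Log2 ratio of the share of windows with a motif, summits over background (x axis), for the 17 motifs (y axis) past the adjusted test in either comparison; grey squares are against windows 500 bp away, circles against GC-matched windows, filled where adjusted p is under 0.05. GAGA stands at 0.66 and 1.41, GATA at 0.47 and 0.02.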

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

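Of the tests below, those of GC composition on X and of GC-matched GAGA were chosen after the result was seen, the test of distal peaks replaced one that did not bear on peak strength, and the GAGA pattern was widened from weaker peaks to all summits after its tests had been run. Some regions lay outside the chromosome arms. The relaxed dm6 list of replicate 1 held 12 mitochondrial regions, against 2 in replicate 2 and 0 in replicate 3, while the dm3 lists of the same replicates held 7, 6 and 4. The strongest region of that whole list, with a signal value of 729, was mitochondrial, while the strongest mitochondrial region of the dm3 list of the same replicate had 21.9. In dm3, 40 pooled relaxed regions lay on sequence other than the arms, Y and mitochondrion, and 3 peaks of the dm3 IDR list lay there, with a signal value of up to 143.

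Summits of stronger peaks were on average more AT-rich, with a mean GC content of 31.8% in the strongest decile and 37.8% in the weakest. The mean changed little from decile 7 (36.9%) to decile 10. Over single IDR peaks the Spearman correlation of signal and GC content was only -0.18. If AT-rich DNA alone decided which regions passed, nearly all of the AT-richest regions would be IDR peaks. Of the lowest GC decile of the pooled list, 31.8% overlapped one (interval 30.3 to 33.4), against 24.6% of the highest. This bears only on composition as the sole cause, since a graded effect of composition would also give a higher share at low GC. Promoter peaks alone did not carry the trend, since among distal peaks the strongest minus the weakest decile was -4.19 percentage points (interval -5.31 to -3.08), though it was -10.4 among promoter peaks (interval -12.1 to -8.72). Nor did 1 library carry it: the strongest minus the weakest decile was -5.81, -6.02 and -5.59 points in replicates 1, 2 and 3. A partial effect of composition on signal stays open, and with 1 group no biological explanation was tested.

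Replicate 2 had fewer X regions, with 17.3% of its 6410 strongest on X against 19.9% and 19.5%, and at 6288 IDR peaks its log2 signal against replicates 1 and 3 was lower on X than on the autosomes (difference -0.11, bootstrap interval -0.14 to -0.07). Composition did not remove it, since the difference weighted over 5 groups of GC content was -0.11 (interval -0.14 to -0.08). The mean log2 ratio was -0.44 on X and from -0.37 (2R) to -0.31 (3R) on the autosome arms, and the X difference between replicates 1 and 3 was -0.021 (interval -0.054 to 0.0099); these intervals are over peaks, and with 3 libraries and X singled out from the data, chance variation between libraries stays open. A larger share of males in the pool of replicate 2 stays open with no test here that bears on it, since the ratio of the sexes was not given in the labels and any difference along the whole of X would look alike in these lists.

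GAGA was the motif with the lowest adjusted p once GC content was matched, with a log2 ratio of 1.41 (exact adjusted p = 1.28e-17), so the GC content of the flanks is not its source. The rarer CLAMP site had a larger ratio (3.47, against 2.65 for GAGA). Promoter peaks alone did not carry it, since distal peaks had a log2 ratio of 0.92 (2.46% against 1.29%, exact p = 1.05e-04), though promoter peaks had 6.66% against 2.22%. Long GA repeats did not carry it either: without windows holding a GA repeat of 10 bases or more, the log2 ratio was 1.17 (exact p = 2.16e-10). Whether libraries of pupae without the tagged protein would show the same excess stays open, since none was analysed here, and with 1 group no biological explanation was tested.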

How the results depend on the processing

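The alternatives added after seeing the data were GC-matched windows, lists without misplaced members and the X share per replicate. The promoter share kept its direction and call under every alternative (log2 odds ratio 1.11 to 1.92). The share of peaks with full support was 59.3% with 50% of the peak covered, 53.9% with summits within 100 bp and 94.1% with 2 times as many regions per replicate; it was 71.8% to 75.3% without 1 replicate, where fewer replicates have to agree. Rank agreement without 1 replicate is the correlation of the remaining pair, 0.70 to 0.77, so it adds nothing to the 3 correlations given above. The promoter against distal difference was 0.017 on the log2 scale with starts within 250 bp and 155 ranks with averaged ranks, neither past the threshold, 0.13 among peaks with full support and 0.054 to 0.11 without 1 replicate, not past it without replicate 3; the cause was not tested. The X share passed the test only against the bases of the arms (log2 odds ratio 0.15). Lists past the test numbered 3 in the main analysis, 1 with starts within 250 bp, 0 among the 3205 strongest peaks (3 at an unadjusted Fisher's exact p under 0.05), 1 among peaks with full support, 8 against all protein-coding genes and 1 to 2 without 1 replicate. Motifs more frequent at summits numbered 4 among the 3205 strongest peaks, 3 against relaxed regions and 2 against GC-matched windows, where hexamers numbered 103; the matched windows remove composition by construction, and the cause was not tested for the other 2. Among the 16 motifs past the test, log2 ratios that changed sign were forkhead (-0.025), homeobox (-0.21) and Hox-Exd (-0.20) against GC-matched windows and Hox-Exd against relaxed regions (-0.0064). The own locus held 3 peaks in a 10 kb window (94.2 percentile) and 6 in a 50 kb window (87.0 percentile). In the 20 kb window it held 2 to 3 without 1 replicate. Settings for single lists were counted only for the 7 lists with an unadjusted Fisher's exact p under 0.05. Of these settings 46 kept their side of the threshold, 13 lost the call and 4 gained one. All 13 losses fell on the 3 lists past the test, since a list not past it has no call to lose. Leaving out misplaced members could change only the cuticle list among the 7. For the 16 single motifs 94 settings kept their side of the threshold and 50 lost the call, among them the 4 settings with a changed sign. The mean rank of a named peak over 2 replicates always lies within the range of the 3, so it says nothing on stability; that of the dnr1 peak, named by its nearest start CG11362, went from 54.7 to 8.5 without replicate 2. Depth is unknown, so no limit from depth can be given.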

Other observations

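The counts below describe genes and words chosen after seeing the data. Several long genes held many IDR peaks. The largest number was 29 in kirre, which encodes a cell adhesion protein of the immunoglobulin family and spans 394 kb of X (0.0736 peaks per kb against 0.0479 on average over the arms). Next were sbb with 23 peaks (0.291 per kb), CG1677 and Tet with 21 each, shn with 19 (0.326 per kb), and Eip75B, Svil and ush with 18 each. Mnt, which encodes a transcriptional repressor that pairs with Max, held 16 peaks in 29.9 kb, or 0.536 per kb, and EcR, the ecdysone receptor gene, held 11. In all, 233 genes held 5 or more. With overlapping peaks merged into 1 interval, kirre held 28, sbb 19, shn 17, Mnt 14 (0.469 per kb) and EcR 9, and 200 genes held 5 or more.

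Classes of genes differed in how often a relaxed summit near a start was an IDR peak. The share was 46.6% for protein-coding genes (2180 of 4676), 32.2% for ncRNA genes (300 of 932) and 23.8% for tRNA genes (35 of 147, interval 17.2 to 31.5; two-sided Fisher's exact test of tRNA genes against all others, adjusted p = 1.48e-06 over 6 classes). Pseudogenes had 7 of 30 (23.3%, exact p = 0.0267 before adjustment, also past the adjusted threshold) and small nucleolar RNA genes 11 of 29 (exact adjusted p = 0.695). Neighbouring genes that share a summit were counted singly, and separate peaks were not counted for these classes. Such genes are not independent, so the p-values and the interval can overstate the evidence.

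Of 3296 decamers present in at least 20 windows, several with no more than 6 A or T bases shared a core at summits. CACTGAGAGA was found in 37 summit windows, 3 flanks and 8 GC-matched windows (exact sign test of summits against flanks, Bonferroni-adjusted p = 6.42e-05). CTGAGAGAAA was found in 34, 2 and 8, and TCTCAGTGCA in 33, 3 and 6. GAGA was more frequent at the 3205 weaker IDR peaks than at the 3205 stronger (4.65% and 3.40% of summits, odds ratio 1.38, interval 1.08 to 1.78, Fisher's exact p = 0.0131). Against GC-matched windows it was in excess in both sets, with log2 ratios of 1.72 at the weaker peaks and 1.17 at the stronger (exact McNemar p = 3.75e-15 and 5.20e-07).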
